A study of Homo sapiens with 18 samples.

How the data were processed

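Bulk mRNA was sequenced from hiF-T cells, a line of human fibroblast-like cells derived from BJ skin fibroblasts that carries a telomerase (hTERT) transgene. Per the labels, RNA was extracted with the RNeasy Micro kit, poly(A)-selected with the NEBNext module and made into libraries with NEBNext Ultra II. The 18 libraries carry a control guide (4 libraries, 2 guides) or CRISPR guides against CDKN1A (4 libraries, 2 guides), KDM1A (4 libraries, 2 guides) or SPP1 (6 libraries, 3 guides), with biological replicates 1 and 2 for each guide. The series calls the perturbation a knockdown; how the guides lower the mRNA is not given in the sources used here, so the mRNA left is not a measure of the protein lost. The control libraries are titled as backbone, and whether their guides are non-targeting is not given in the sources used here. Whether replicates 1 and 2 are separate transductions or cultures is not given either.

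The authors deposited 1 kallisto table per library, which gives estimated (expected) counts, TPM and effective lengths for 188753 Ensembl transcripts on the human genome build GRCh38. The version of kallisto, its settings and the transcriptome release are not given in the sources used here. The deposited estimated counts are not whole numbers and are not scaled to library size. Only the estimated counts entered the tests, and the effective lengths entered 1 alternative.

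Transcripts were assigned to genes by their Ensembl identifiers with GENCODE 29, which matched 169754 transcripts (89.9%) to 35544 genes. The 18999 unmatched transcripts held 2.51 to 2.63% of the counts of a library and were left out. Genes of the major histocompatibility region (HLA genes, TAP1, TAP2, PSMB8, BAG6) can have counts on alternate haplotype copies, which was not measured here, so their values are treated as uncertain. HIST2H2AA3, TIMM22, PPP4R4, IRF7 and TAP2 went from near 0 to clearly detected within a group, as kallisto's division of reads among near-identical transcripts can give, and are uncertain too. The total estimated count in units of 1e6 was 11.91 to 17.02 per library, and 12471 to 13154 genes per library had at least 10 counts.

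Counts were summed per gene and rounded. Genes were kept by edgeR's filterByExpr by group with a count minimum of 10, which left 13519. With edgeR 4.0.16 in R 4.3.3, libraries were scaled by TMM and a quasi-likelihood model with 1 coefficient per group was fitted to all 18 libraries, without a block, since the labels state no design. In the data the replicate numbers did not pair samples across guides. Adjusted p-values are from edgeR's quasi-likelihood F test with the Benjamini-Hochberg correction over the 13519 genes, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change was computed from it and the F statistic. Fold changes are those of the model fit. The log2 CPM of the list and permutation tests carry a prior count of 2, and CPM are TMM-scaled. The common dispersion was 0.00869, a biological coefficient of variation of 9.32%; with a coefficient per guide it was 0.00478 (6.91%), so libraries of different guides against a target are not equivalent replicates. The 3 knockdowns were compared with control and with each other, and the guides of a target with each other in the fit with a coefficient per guide. Each guide was also set against all control libraries in that fit. Its spread is that between the libraries of a guide, and the guides share the controls, so their calls are not independent of each other. Single target mRNAs also had a two-sided exact permutation test on log2 CPM.

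In all, 26 gene lists, fixed before the data were examined like the groups, the model and the rule for named genes, were tested with limma 3.58.1 camera at a preset correlation between genes of 0.01, 78 tests in 1 Benjamini-Hochberg family. They are G1/S and DNA replication, G2/M and mitosis, p53 targets, CDK inhibitors and pocket proteins, inflammatory cytokines, contractile myofibroblast genes, extracellular matrix, TGF-beta and YAP targets, matrix proteases and inhibitors, osteopontin receptors and SIBLING proteins, pluripotency factors, epithelial genes, mesenchymal genes, the KDM1A-CoREST complex, neuronal REST targets, type I interferon response, antigen presentation, cholesterol synthesis, integrated stress response, hypoxia and glycolysis, iron storage and NRF2 targets, immediate early and heat shock genes, and mitochondrially encoded mRNAs, with markers of keratinocytes, melanocytes, and endothelial cells and leukocytes as other cells a skin-derived culture could hold. A targeted gene was left out of its lists in its own comparison. The named genes are the targeted gene, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and 1 direction in every guide, and in each list up to 4 called members of smallest p, or else its member of smallest p.

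Whether fold changes were shared between knockdowns was measured as the correlation of log2 fold changes across genes, which are not independent replicates. It was set against 20 simulated data sets without any shared effect that keep the common control, and against fold changes computed with a different control guide for each knockdown. The procedure was tested on simulated data. Counts were drawn at the control means with the library sizes and spread of the data, and known genes were changed. Libraries were drawn independently, without guide effects, so the rates below leave such effects out. For the CDKN1A comparison 83.7% of genes changed 2-fold were recovered and 32% of those changed 1.25-fold, with 4.7% false calls; for KDM1A these were 91.8%, 46% and 7.7%, and for SPP1 76%, 32% and 4.3%.

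The alternatives were DESeq2's Wald test (1.42.0) and size factors, no filter or a minimum of 50, an offset for average transcript length, a replicate block, the 2 compared groups alone, both libraries of a guide summed, each library or guide left out in turn, an estimated correlation in camera, and, chosen after seeing the data, leaving out 2 libraries. Figures were drawn with matplotlib 3.10.9, and tables made with pandas 2.3.3.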

Results

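The data are poly(A) RNA-seq counts from hiF-T cells, human fibroblast-like cells that can be reprogrammed to pluripotency, after CRISPR knockdown of CDKN1A, KDM1A or SPP1 or with a control guide. The control, CDKN1A and KDM1A groups held 4 libraries each and the SPP1 group 6, from 2, 2, 2 and 3 guides with 2 biological replicates per guide. The total estimated count in units of 1e6 was 14.74 ± 0.977 (SD, n = 4) for control, 14.858 ± 1.259 (n = 4) for CDKN1A, 15.102 ± 1.795 (n = 4) for KDM1A and 13.868 ± 1.988 (n = 6) for SPP1. Mitochondrial genes held 1.81 to 2.42% of counts per library. Of the variance between libraries across genes, 31.6% lay between groups, 28.9% between guides of a group and 39.5% between libraries of a guide. These are shares of sums of squares on 3, 5 and 9 degrees of freedom. Per degree of freedom, the value between groups was 1.82 times that between guides. Gene values are given as mean CPM ± SD over these libraries (n = 4, or 6 for SPP1 knockdown) or as log2 fold change ± SE, and adjusted p-values are edgeR's.

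Each targeted mRNA was first measured in its own knockdown. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339, GRCh38), which encodes the CDK inhibitor p21, fell to 58.2% of control, from 612 ± 65.9 to 357 ± 86.2 CPM (adjusted p 0.00395). KDM1A (ENSG00000004487, chromosome 1, 23019443 to 23083689), the histone demethylase LSD1, fell to 52.9% of control, from 118 ± 6.03 to 62.7 ± 13.1 CPM (adjusted p 7.26e-06). SPP1 (ENSG00000118785, chromosome 4, 87975650 to 87983426), the secreted protein osteopontin, measured 61.4% of control, 39.7 ± 17.8 against 64.6 ± 7.27 CPM, which did not pass (adjusted p 0.0696, lower than every control in 4 of 6 libraries). Two-sided exact permutation p-values were 0.0286 for CDKN1A and for KDM1A, the smallest that the 70 arrangements allow, and 0.0476 for SPP1. The arrangements count the libraries of a guide as separate samples, and whole guides are too few for a small p.

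Each guide was also set against all control libraries in the fit with a coefficient per guide, whose smaller spread can give smaller p-values than the group fit. CDKN1A mRNA was at 46.3% of control with guide 1 and 70.6% with guide 2 (adjusted p 4.10e-06 and 0.00243). KDM1A mRNA was at 62.6% with guide 2 and 43.4% with guide 3 (adjusted p 5.17e-07 and 5.23e-09). SPP1 mRNA was at 39.6% with guide 1 (adjusted p 0.00827), 79.7% with guide 2 (0.443) and 66.8% with guide 3 (0.144), whose replicates measured 63 and 21.7 CPM. SPP1 mRNA rose to 205% of control in the KDM1A knockdown (132 ± 4.17 CPM, adjusted p 0.00793) and measured 181% in the CDKN1A knockdown (117 ± 16 CPM, adjusted p 0.0645). The CDKN1A fall was not called without control guide 1 (log2 -0.66, adjusted p 0.0834), and SPP1 mRNA passed without SPP1 guide 3 replicate 1 (log2 -0.89, adjusted p 0.0248).

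**Figure D1:**
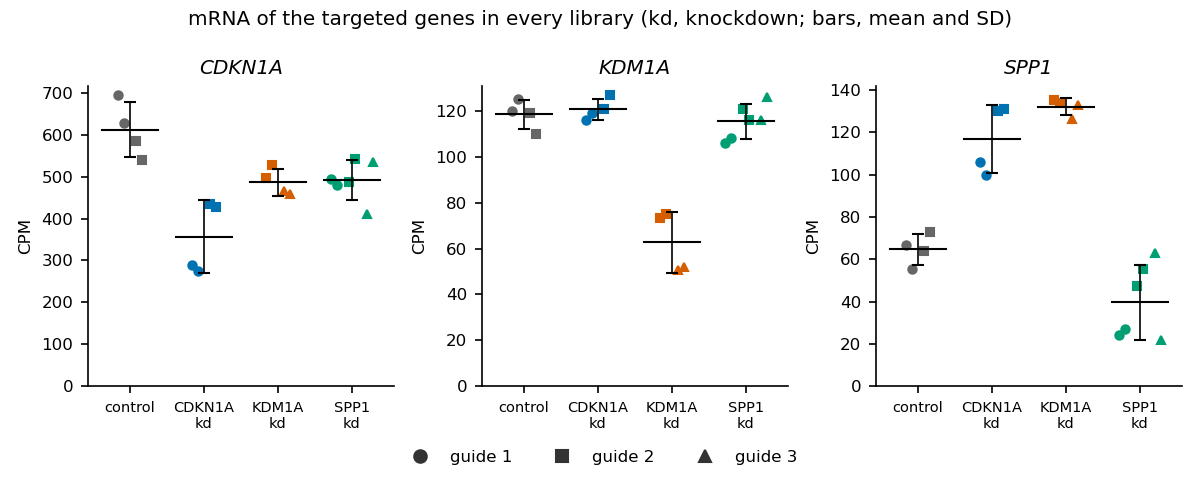
CPM of CDKN1A, KDM1A and SPP1 in every library, by group, with marker shape for the guide and bars for the mean and SD (n = 4, and 6 for SPP1 knockdown). KDM1A mRNA in its knockdown lies at 62.7 ± 13.1 CPM, while SPP1 mRNA in its knockdown spreads around 39.7 ± 17.8 CPM.

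The CDKN1A knockdown addressed which transcripts follow a lower level of p21, which halts the cell cycle downstream of p53. TNFSF9, which encodes the T-cell co-stimulatory ligand 4-1BBL, rose 6.53-fold from 1.03 ± 0.662 to 6.82 ± 0.998 CPM (adjusted p 0.00125), above every control in 4 of 4 libraries. GASK1B rose 2.03-fold, from 18.3 ± 3.45 to 37.2 ± 2.57 CPM (adjusted p 1.55e-05), and CAVIN2, a caveolar coat protein, 1.99-fold (adjusted p 0.00179). Among the falls were CRYAB, a small heat shock chaperone (log2 -1.69 ± 0.32, adjusted p 0.0128), the chitin-binding receptor FIBCD1 (-1.09 ± 0.14, 7.83e-04) and EDN1, the vasoconstrictor endothelin-1, from 126 ± 9.27 to 70.5 ± 1.55 CPM (adjusted p 0.0238). In all, 271 of 13519 genes changed, 147 upward and 124 downward, of which 23 changed at least 2-fold. Of the 271, 182 were called with each guide alone, in the fit with a coefficient per guide and against the same controls. Other large rises were PAPPA2, UNC5B, GAL3ST4, PTCHD4, TMCC3, ZNF85 and EPGN (log2 0.95 to 1.94), and other large falls were FOSB, FOS, SLFNL1, MEGF6, TINAGL1 and SLC1A1 (log2 -1.98 to -0.83) and the receptor NOTCH3, which halved from 14.3 ± 2.88 to 7.11 ± 1.44 CPM.

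p53 targets other than CDKN1A were raised. Of 23 measured, 6 rose and 0 fell (11 and 0 adjusted over the list alone), with a median log2 fold change of 0.23 and an adjusted p of 1.06e-06, or an adjusted p of 0.0902 with an estimated correlation. GDF15, a stress-induced cytokine, went from 131 ± 11.4 to 203 ± 6.24 CPM (adjusted p 0.00138). RRM2B, the p53-inducible ribonucleotide reductase subunit, went from 52.1 ± 1.92 to 75.3 ± 1.5 CPM (0.00409). TP53INP1 (log2 0.53 ± 0.1) and the DNA damage sensor DDB2 (0.32 ± 0.07) rose too. In the G2/M and mitosis list 2 of 23 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p 8.09e-05, or adjusted p 0.477 with an estimated correlation). These were the kinetochore protein CENPF (299 ± 17.6 to 364 ± 4.12 CPM) and the cyclin CCNB2 (53.6 ± 5.22 to 65.4 ± 2.65 CPM). No G1/S and DNA replication gene of 23 was called (adjusted p of the list 0.821). CDK inhibitors and pocket proteins had 1 rise in 10, RBL2, a relative of RB1 (log2 0.33 ± 0.07; 2 rises adjusted over the list alone; list adjusted p 0.00647, and adjusted p 0.067 with an estimated correlation).

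The integrated stress response list had 2 rises in 14 (7 rises and 1 fall adjusted over the list alone; adjusted p 0.00501, or adjusted p 0.537 with an estimated correlation). They were TRIB3, a pseudokinase induced by ATF4 and CHOP (23.2 ± 2.04 to 39.3 ± 11.8 CPM), and the lipoprotein receptor VLDLR (11.3 ± 1.94 to 17.8 ± 2.67 CPM). No member of 11 in the iron storage and NRF2 list was called (0 adjusted over the list alone; median 0.14, list adjusted p 0.0164, or adjusted p 0.583 with an estimated correlation). Without CDKN1A guide 2 the adjusted p-values of the stress and iron lists were 0.58 and 0.757.

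Of the lists that passed downward, few members were called. In the contractile myofibroblast list 1 of 15 fell, the actin-binding calponin CNN2 (log2 -0.44 ± 0.1; 8 falls adjusted over the list alone; list adjusted p 1.32e-04, or adjusted p 0.537 with an estimated correlation). Of 26 extracellular matrix genes 0 were called (1 rise and 1 fall adjusted over the list alone; list adjusted p 0.00757, or adjusted p 0.583 with an estimated correlation). COL6A1 had log2 -0.22 ± 0.06 (adjusted p 0.0579). Of 8 epithelial genes the keratins KRT18 (550 ± 32.1 to 410 ± 30.8 CPM, adjusted p 0.00817) and KRT8 (83.1 ± 1.55 to 57.3 ± 1.43 CPM, 0.0176) fell (3 falls adjusted over the list alone; list adjusted p 0.0344, or adjusted p 0.339 with an estimated correlation). Cholesterol synthesis had 0 calls in 21 (1 rise and 4 falls adjusted over the list alone; list adjusted p 0.00191, or adjusted p 0.581 with an estimated correlation). DHCR7 had log2 -0.37 ± 0.1 (adjusted p 0.0514). Of 17 immediate early and heat shock genes the transcription factors FOS, FOSB and KLF2 fell (5 falls adjusted over the list alone; list adjusted p 0.0162, or adjusted p 0.0902 with an estimated correlation). FOS and FOSB averaged 31.7 and 25 CPM in control guide 1 but 8.89 and 5.53 CPM in control guide 2. Without control guide 1 the epithelial, cholesterol synthesis, and immediate early and heat shock lists had adjusted p 0.15, 0.143 and 0.0752, while the p53 targets had 4.54e-12.

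The other 16 lists did not pass (adjusted p 0.0568 to 0.966). Among TGF-beta and YAP targets 2 of 26 fell (1 rise and 4 falls adjusted over the list alone), among them the matricellular protein CCN2, from 1350 ± 146 to 871 ± 57.9 CPM. Neuronal REST targets went both ways (9 measured, 1 rise and 2 falls; 2 and 4 adjusted over the list alone): the neurotrophin BDNF (176 ± 5.83 to 125 ± 13.6 CPM, adjusted p 0.00608) and SCG2 fell and the sodium channel SCN2A rose. Single members were called in 5 lists: the cytokine IL11 (log2 -0.65 ± 0.13), the protease ADAMTS1 (-0.45 ± 0.1), the integrin ITGA5 (-0.29 ± 0.07), the hexokinase HK2 (-0.26 ± 0.06) and, among keratinocyte markers, PERP (0.27 ± 0.07). No member of the pluripotency, mesenchymal, KDM1A-CoREST, interferon, antigen presentation, mitochondrial, melanocyte, or endothelial and leukocyte lists was called. The telomerase TERT, which the line also carries as a transgene, had log2 -0.3 ± 0.08 (adjusted p 0.0582).

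The number of CDKN1A calls was 42 without control guide 1, 127 without CDKN1A guide 1, 44 without CDKN1A guide 2, 1 with both libraries of a guide summed, 71 with a transcript length offset, 587 with the 2 groups alone and 561 with DESeq2. Leaving out 1 library gave 66, 132 and 89 without control guide 1 replicates 1 and 2 and control guide 2 replicate 1. It gave 121, 99, 102 and 54 without CDKN1A guide 1 replicates 1 and 2 and guide 2 replicates 1 and 2, and 446 without SPP1 guide 3 replicate 2. Of the 43 called named genes all kept their direction without control guide 1, and 13 kept the call there. The call held whichever library was left out for 14, TNFSF9, GASK1B, CAVIN2, GDF15, TP53INP1, KRT18 and BDNF among them.

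**Figure D2:**
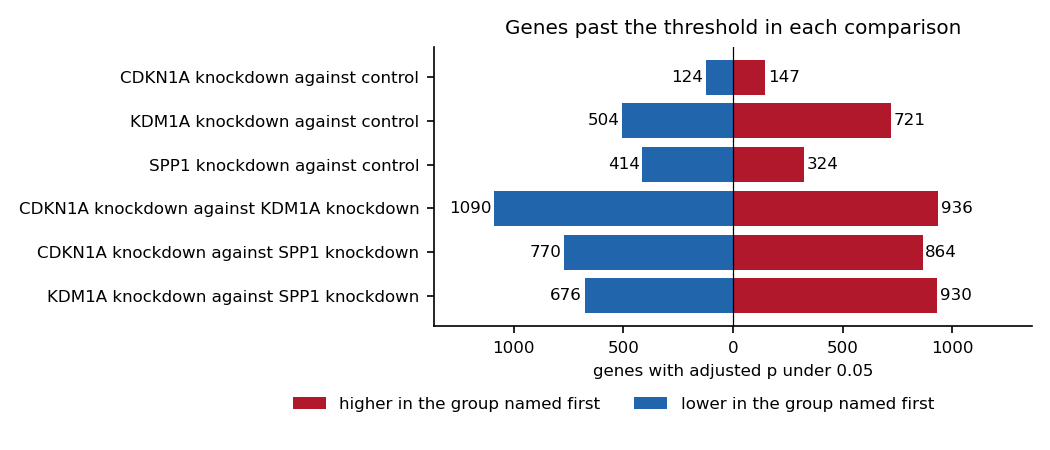
Genes with adjusted p under 0.05 in the 6 comparisons, with bars to the right for genes higher and to the left for genes lower in the group named first. Calls against control ranged from 271 for CDKN1A to 1225 for KDM1A.

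The KDM1A knockdown addressed which transcripts follow a lower level of LSD1, which removes methyl groups from histone H3 as part of the CoREST repressor complex. LUM, the matrix proteoglycan lumican, rose 13.8-fold, from 1.26 ± 0.319 to 17.5 ± 3.09 CPM (adjusted p 1.75e-07). The fibrillar collagen COL3A1 rose 7.23-fold (log2 2.85 ± 0.27, adjusted p 2.04e-06), the tight junction protein CLDN1 5.38-fold (10.1 ± 2.97 to 54.2 ± 17.2 CPM, 2.39e-06) and the growth factor EPGN 4.79-fold (3.03 ± 1.36 to 14.4 ± 1.3 CPM, 2.39e-06). LZTS1, TMEM98 and the T-box factor TBX15 fell 4.25-fold, 3.91-fold and 3.37-fold (adjusted p 4.67e-06, 6.74e-06 and 4.99e-06), each below every control in 4 of 4 libraries.

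Of 13519 genes 1225 changed, 721 upward and 504 downward, and 204 changed at least 2-fold, 139 of them upward. Of the 1225, 711 were called with each guide alone. Further rises were the acetylcholine receptor subunit CHRNB1, the laminin receptor subunit ITGA7, the junction protein JUP, IFI44L, LRRC17 and SERPINB2 (log2 2.11 to 3.21). Further falls were FOSB, AKR1C1, PTPRN, the stress-induced factor ATF3, the potassium channel subunit KCNG1, the TGF-beta feedback gene PMEPA1 and PPP4R4, whose value is uncertain (log2 -2.62 to -1.69).

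p53 targets fell: of 24 measured 12 fell and 0 rose (16 falls adjusted over the list alone), with a median log2 fold change of -0.3 and an adjusted p of 2.72e-08, or an adjusted p of 0.067 with an estimated correlation. SESN2, a stress-inducible inhibitor of mTORC1, went from 13.3 ± 1.07 to 7.02 ± 0.407 CPM (adjusted p 3.35e-05), and GDF15 from 131 ± 11.4 to 81.4 ± 3.64 CPM (1.11e-04). The antiproliferative gene BTG2 (log2 -1.28 ± 0.27) and the DNA damage gene GADD45A (-0.4 ± 0.09) fell as well. Without control guide 1 these last 2 were not called (-0.99 and -0.33), while the list had adjusted p 3.40e-05. The integrated stress response fell with them, 6 of 14 members lower and 0 higher (1 rise and 8 falls adjusted over the list alone; median -0.39, adjusted p 1.32e-04, or adjusted p 0.383 with an estimated correlation). ATF3 went from 12.4 ± 2.79 to 3.72 ± 0.666 CPM, and DDIT3, which encodes the factor CHOP, from 14.2 ± 0.761 to 8.69 ± 1.32 CPM. The glutathione-degrading enzyme CHAC1 (log2 -0.62 ± 0.12) and ATF4, the central factor of the response (-0.35 ± 0.07), also fell.

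Type I interferon response genes rose, 5 of 18 higher and 0 lower (7 rises adjusted over the list alone; median 0.14, adjusted p 0.00358, or adjusted p 0.067 with an estimated correlation). IFI44L went from 1.58 ± 0.633 to 7 ± 0.701 CPM (adjusted p 5.95e-05) and the RNA-sensing enzyme OAS3 from 3.06 ± 0.641 to 7.79 ± 1.28 CPM (0.00177), with IFI44 (log2 0.94 ± 0.15) and the ISG15 protease USP18 (0.8 ± 0.14). Antigen presentation genes rose too, 4 of 9 higher and 0 lower (5 rises adjusted over the list alone; median 0.37, adjusted p 0.00718, or adjusted p 0.067 with an estimated correlation). B2M, the light chain of class I molecules, went from 324 ± 33.6 to 419 ± 33.4 CPM (adjusted p 0.00518) and its transcriptional activator NLRC5 from 24.8 ± 4.08 to 33.2 ± 0.968 CPM (0.00528). TAP1 and PSMB8 also passed, but lie in the region with alternate copies. Without KDM1A guide 3 the interferon list had adjusted p 0.115, and without KDM1A guide 2 the antigen presentation list had 0.0651.

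The other 22 lists did not pass (adjusted p 0.0568 to 0.943). In the extracellular matrix list 3 of 26 rose and 1 fell (6 and 3 adjusted over the list alone): LUM, COL3A1 and the proteoglycan DCN (6.49 ± 2.4 to 24.2 ± 1.32 CPM) rose and FBLN2 fell. Among TGF-beta and YAP targets 1 of 26 rose and 4 fell (1 and 4 adjusted over the list alone), among them TGFBI (2570 ± 264 to 1430 ± 306 CPM) and PMEPA1, while FJX1 rose. Neuronal REST targets, which the CoREST complex can repress, had 2 rises in 9 (2 rises and 1 fall adjusted over the list alone; list adjusted p 0.148): SCN2A (3.81 ± 0.31 to 9.6 ± 0.392 CPM, adjusted p 6.74e-06) and the synaptic vesicle protein SYT1 (23 ± 0.678 to 33.5 ± 1.78 CPM, 3.76e-04). No other of the 10 measured members of the KDM1A-CoREST complex was called.

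Epithelial genes split, the desmosomal DSP falling from 179 ± 23.5 to 85.2 ± 7.61 CPM and KRT19 rising from 0.885 ± 0.253 to 2.74 ± 0.552 CPM (8 measured; 2 rises and 1 fall adjusted over the list alone). Inflammatory cytokines had 1 rise and 2 falls in 15 (2 and 2 adjusted over the list alone): LIF rose, and IL11 (log2 -0.82 ± 0.13) and the prostaglandin synthase PTGS2 (-1.02 ± 0.18) fell. PLAU, the urokinase protease, rose from 78.2 ± 3.29 to 150 ± 1.83 CPM (adjusted p 1.07e-05) and MMP3 fell. Osteopontin receptors and SIBLING proteins had a rise in SPP1 and a fall in ITGB3 (28.7 ± 7.52 to 16.4 ± 4.54 CPM), which was not called without control guide 1 (log2 -0.44 against -0.81). The mesenchymal genes SNAI1 and PDGFRB and the contractile SYNPO2 rose. The CDK inhibitor CDKN2B, TERT (log2 -0.32 ± 0.08), ADM, the NRF2 target GCLM and, of the immediate early genes, ATF3, FOS and FOSB fell. Without control guide 1 FOS and FOSB were not called (log2 -0.48 and -1.03, against -1.67 and -2.49). Among keratinocyte markers PERP, a desmosomal p53 target, rose from 61.3 ± 6.47 to 107 ± 6.93 CPM (adjusted p 4.68e-07). No gene of the G1/S, G2/M, mitochondrial, melanocyte, or endothelial and leukocyte lists was called.

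The number of KDM1A calls was 417 without control guide 1, 747 without KDM1A guide 2, 570 with a transcript length offset, 162 with both libraries of a guide summed and 774 without control guide 1 replicate 2. All 60 called named genes kept their direction without control guide 1 and 36 kept the call, and 46 kept it whichever library was left out.

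**Figure D3:**
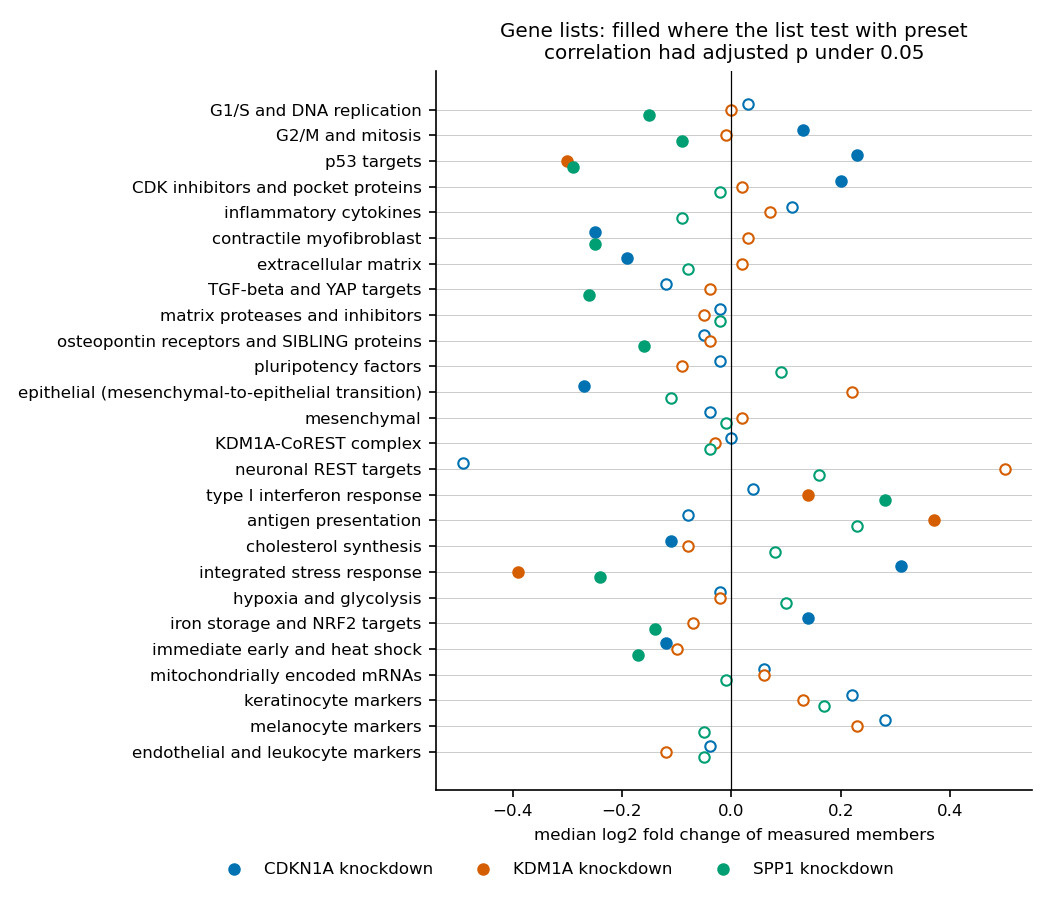
Median log2 fold change of the measured members of each of the 26 gene lists in the 3 knockdowns against control, filled where the list test with the preset correlation had an adjusted p under 0.05. The p53 targets have medians of 0.23 for CDKN1A, -0.3 for KDM1A and -0.29 for SPP1; none of the 78 tests passed with an estimated correlation.

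The SPP1 guides were meant to lower osteopontin, but SPP1 mRNA itself did not pass the test, so the changes below are those of the guides. GDF15 fell from 131 ± 11.4 to 76 ± 11.6 CPM (adjusted p 2.36e-04), and KLF2, a flow- and stress-responsive transcription factor, from 115 ± 4.61 to 73.9 ± 4.9 CPM (5.90e-04). The VEGF receptor FLT1 fell 3.06-fold (10.1 ± 0.734 to 3.23 ± 1.59 CPM, adjusted p 0.00291), ATF3 2.74-fold (0.00209) and the phospholipid flippase ATP10A 2.48-fold (0.00536), each in 6 of 6 libraries below every control. EPGN rose 2.65-fold (adjusted p 0.0024), the neuronal pentraxin NPTX1 2.15-fold, from 60.4 ± 16.1 to 130 ± 38.7 CPM (0.00573), and the phospholipase PLA2G4A 1.86-fold (0.00288). Of 13519 genes 738 changed, 324 upward and 414 downward. At least 2-fold changes numbered 53, 47 of them downward, and 240 of the 738 were called with each guide alone. The number of calls did not rise with the loss of SPP1 mRNA, which does not measure the loss of protein. Guide 1, the only one whose SPP1 mRNA passed as lower (39.6% of control), gave 619 calls, and guides 2 and 3 (79.7% and 66.8%) gave 1438 and 1425. Guide 2 and guide 3 replicate 2 also had the lowest total counts (11.91, 12.1 and 12.34 in units of 1e6) and the largest median length minus effective length (223.3, 209.6 and 204.7 bases, against at most 197.1). For the other targets too, the guide with the larger loss of its mRNA gave fewer calls. KDM1A guide 3 (43.4% of control) gave 1557 and KDM1A guide 2 (62.6%) 1909. CDKN1A guide 1 (46.3%) gave 637 and CDKN1A guide 2 (70.6%) 842.

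Further rises were COL3A1, DGKG, GDF5, TMEM132B, NCKAP5 and DPP4 (log2 0.85 to 1.1), and further falls TMEM200C, FOSB, MSC, DACT1 and GFRA1 (log2 -1.69 to -1.2). HIST2H2AA3 (log2 4.91 ± 1.42), TIMM22 (-6.76 ± 1.78) and BAG6 (-1.52 ± 0.37) also passed, but their values are uncertain.

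p53 targets fell, 11 of 24 lower and 0 higher (1 rise and 18 falls adjusted over the list alone), with a median of -0.29 and an adjusted p of 8.76e-09, or an adjusted p of 0.067 with an estimated correlation. Beside GDF15 they were led by GADD45A (175 ± 12.3 to 126 ± 16 CPM), SESN2 (13.3 ± 1.07 to 9.26 ± 1.26 CPM) and DDB2 (33.1 ± 3.53 to 26.8 ± 1.85 CPM). In the G1/S and DNA replication list 4 of 23 fell (10 adjusted over the list alone; median -0.15, adjusted p 6.59e-06, or adjusted p 0.477 with an estimated correlation): the replication licensing and initiation factors CDC6, CDT1 and CDC45 and the thymidylate synthase TYMS, with log2 fold changes of -0.31 to -0.2. In the G2/M list CDK1, the mitotic kinase, fell (1 of 23; 2 adjusted over the list alone; list adjusted p 0.00718, or adjusted p 0.583 with an estimated correlation).

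TGF-beta and YAP targets fell, 7 of 26 lower and 0 higher (11 falls adjusted over the list alone; median -0.26, adjusted p 4.83e-06, or adjusted p 0.144 with an estimated correlation). CCN2 went from 1350 ± 146 to 878 ± 139 CPM (adjusted p 0.00573), and the inhibitors of the pathway SKIL (log2 -0.53 ± 0.11) and SMAD7 (-0.74 ± 0.17) fell. Contractile myofibroblast genes fell with them, 4 of 15 (5 adjusted over the list alone; adjusted p 0.00501, or adjusted p 0.583 with an estimated correlation): tropomyosin TPM1 (1480 ± 155 to 947 ± 114 CPM), filamin FLNA (5950 ± 393 to 4810 ± 264 CPM), TGFB1I1 and ACTN1. The median of this list was 0 to -0.32 by guide, and it was lower with guides 2 and 3 than with guide 1 (-0.28 and -0.27, adjusted p 2.94e-06 and 2.95e-05, or adjusted p 0.222 and 0.257 with an estimated correlation). The integrated stress response had 2 falls in 14, ATF3 and ATF4 (3 adjusted over the list alone; median -0.24, adjusted p 1.32e-04, or adjusted p 0.383 with an estimated correlation). Of 17 immediate early and heat shock genes 6 fell (1 rise and 7 falls adjusted over the list alone; adjusted p 0.00718, or adjusted p 0.067 with an estimated correlation), KLF2, ATF3, EGR1 and FOSB among them. Iron storage and NRF2 targets had 2 falls in 11 (2 adjusted over the list alone; adjusted p 0.00718, or adjusted p 0.572 with an estimated correlation): the heme oxygenase HMOX1 (53.6 ± 8.09 to 24.8 ± 5.33 CPM) and GCLM. The integrin ITGB3, an osteopontin receptor subunit, fell from 28.7 ± 7.52 to 17.3 ± 1.55 CPM (log2 -0.74, and -0.37 and not called without control guide 1), 1 of 8 in its list (1 rise and 4 falls adjusted over the list alone; adjusted p 0.0445, or adjusted p 0.537 with an estimated correlation).

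The interferon list was the only one to pass upward, with 0 of 18 members called (2 rises adjusted over the list alone; median 0.28, adjusted p 0.00647, or adjusted p 0.067 with an estimated correlation). USP18 had log2 0.42 ± 0.13 (adjusted p 0.0575). The other 16 lists did not pass (adjusted p 0.128 to 0.947). Of 26 matrix genes COL3A1 rose and 4 fell (1 and 7 adjusted over the list alone). The falls included the proteoglycan VCAN (449 ± 30.1 to 306 ± 43.7 CPM) and the basement membrane collagens COL4A1 (1230 ± 107 to 701 ± 93 CPM) and COL4A2. The collagenase MMP1 rose from 6310 ± 622 to 10400 ± 1060 CPM (adjusted p 0.0174) and PLAU from 78.2 ± 3.29 to 108 ± 19.4 CPM (0.0114). DSP fell from 179 ± 23.5 to 108 ± 22.5 CPM (0.00288) and N-cadherin, CDH2, from 433 ± 28.3 to 274 ± 38.7 CPM (0.0126). NFKBIA, PTGS2, the pocket protein RBL1, PODXL, the glucose transporter SLC2A1 and the endothelial receptor TEK (82.4 ± 4.54 to 62.9 ± 6.34 CPM) fell; LDHA and PERP rose. No gene of the KDM1A-CoREST, REST target, antigen presentation, cholesterol, mitochondrial or melanocyte lists was called.

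The number of SPP1 calls depends on control guide 1, whose loss also leaves 2 control libraries. In a fit with the control guides as separate groups, 774 genes were called against control guide 1 and 18 against control guide 2. Both counts rest on 2 control libraries, so fewer control libraries alone do not account for that difference. Leaving out control guide 1 left 7 called genes, and GDF15 and KLF2 were the only 2 of the 58 called named genes to keep the call, although all 58 kept their direction. Some fold changes shrank there, FOSB from log2 -1.48 to -0.02, PTGS2 from -0.68 to -0.18 and DACT1 from -1.25 to -0.59. Others stayed about as large, FLT1 at -1.57, PLA2G4A at 0.87, VCAN at -0.54, SMAD7 at -0.78 and NFKBIA at -0.62. CDT1, TYMS and CDK1 lost the call in 11, 14 and 14 of the 18 fits with 1 library left out. Without its replicate 1 or 2 the count was 364 or 184. Without this guide the G2/M, osteopontin receptor, and immediate early lists had adjusted p 0.244, 0.0741 and 0.113, while the p53 targets had 1.41e-04. It was 445 without SPP1 guide 2 replicate 2, 276 and 432 without SPP1 guides 2 and 3, 293 without control guide 1 replicate 1 and SPP1 guide 3 replicate 2 together, 304 with a transcript length offset, 390 with the 2 groups alone and 1 with both libraries of a guide summed.

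Compared with each other, the knockdowns differed in p53 targets and stress genes. GDF15 was 2.5-fold higher in the CDKN1A than in the KDM1A knockdown (203 ± 6.24 against 81.4 ± 3.64 CPM, adjusted p 9.36e-08) and 2.67-fold higher than in the SPP1 knockdown (adjusted p 3.47e-09). Of 23 p53 targets 17 were higher and 0 lower in the CDKN1A than in the KDM1A knockdown (21 and 0 adjusted over the list alone; median 0.44, adjusted p 3.01e-15, and adjusted p 0.0193 with an estimated correlation). Against the SPP1 knockdown 17 were higher and 0 lower (20 and 0 adjusted over the list alone; median 0.41, adjusted p 6.67e-17, and adjusted p 0.0193 with an estimated correlation). Between the KDM1A and SPP1 knockdowns 0 p53 targets were higher and 2 lower (2 adjusted over the list alone; adjusted p 0.639), and GDF15 differed by log2 0.1 ± 0.09. Stress response genes were higher with CDKN1A than with KDM1A knockdown in 11 of 14 and lower in 1 (12 and 1 adjusted over the list alone; median 0.86, adjusted p 1.43e-07, or adjusted p 0.217 with an estimated correlation). They were higher than with SPP1 knockdown in 11 of 14 (11 adjusted over the list alone; median 0.55, adjusted p 2.07e-08, or adjusted p 0.195 with an estimated correlation). TRIB3, at 39.3 ± 11.8 CPM in the CDKN1A knockdown, measured 19.9 ± 1.64 and 18.9 ± 2.07 CPM in the others. By CDKN1A guide it was 29.2 and 28.9 CPM with guide 1, and 49.5 and 49.4 CPM with guide 2.

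Proliferation lists differed in some pairs, at the preset correlation only. In the G1/S and DNA replication list 7 of 23 were higher in the CDKN1A than in the SPP1 knockdown (9 adjusted over the list alone). That list had adjusted p 2.89e-05, or adjusted p 0.49 with an estimated correlation. Between the CDKN1A and KDM1A knockdowns 0 of its 23 members were called (list adjusted p 0.639). In the G2/M list 12 of 23 were higher in the CDKN1A than in the SPP1 knockdown (14 adjusted over the list alone; median 0.21, adjusted p 1.13e-08, or adjusted p 0.238 with an estimated correlation), with CENPF at 364 ± 4.12 against 290 ± 21.4 CPM. In the same list 5 of 23 were higher than in the KDM1A knockdown (8 adjusted over the list alone; adjusted p 8.49e-04, or adjusted p 0.564 with an estimated correlation). Cholesterol synthesis had 9 of 21 members lower in the CDKN1A than in the SPP1 knockdown (11 adjusted over the list alone; adjusted p 3.83e-05, or adjusted p 0.479 with an estimated correlation). The extracellular matrix list had 1 of 26 members higher and 8 lower in the CDKN1A than in the KDM1A knockdown (1 and 9 adjusted over the list alone; adjusted p 0.00659, or adjusted p 0.564 with an estimated correlation). The KDM1A guides lay on both sides for COL4A1, at 1560 CPM with guide 2 and 614 CPM with guide 3 against 803 ± 118 CPM in the CDKN1A knockdown. LUM was 9.94-fold higher in the KDM1A than in the CDKN1A knockdown (adjusted p 3.71e-07) and 9.41-fold higher than in the SPP1 knockdown (7.07e-08). CLDN1 was 7.01-fold higher than in the SPP1 knockdown (1.05e-07), and IFI44L was 3.68-fold and 3.38-fold higher. Antigen presentation genes were lower in 4 of 9 in the CDKN1A than in the KDM1A knockdown (4 adjusted over the list alone; adjusted p 0.00215, or adjusted p 0.0656 with an estimated correlation). SPP1 mRNA was 2.94-fold and 3.33-fold higher in the CDKN1A and KDM1A knockdowns than in the SPP1 knockdown (adjusted p 1.70e-04 and 3.01e-05).

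In number, 2026 genes differed between the CDKN1A and KDM1A knockdowns (936 higher in CDKN1A), 1634 between CDKN1A and SPP1 (864 higher in CDKN1A) and 1606 between KDM1A and SPP1 (930 higher in KDM1A). Leaving out CDKN1A guide 2 gave 668 for the first and 299 for the second, and leaving out KDM1A guide 2 gave 260 for the third. Single libraries of these 2 guides lowered the first count to 1293 (CDKN1A guide 2 replicate 2) and 1345 (KDM1A guide 2 replicate 2), the second to 864 and 863 (CDKN1A guide 2 replicates 1 and 2), and the third to 801 and 775 (KDM1A guide 2 replicates 1 and 2). With both libraries of a guide summed the counts were 436, 111 and 245, and with a transcript length offset 987, 765 and 762.

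**Figure D4:**
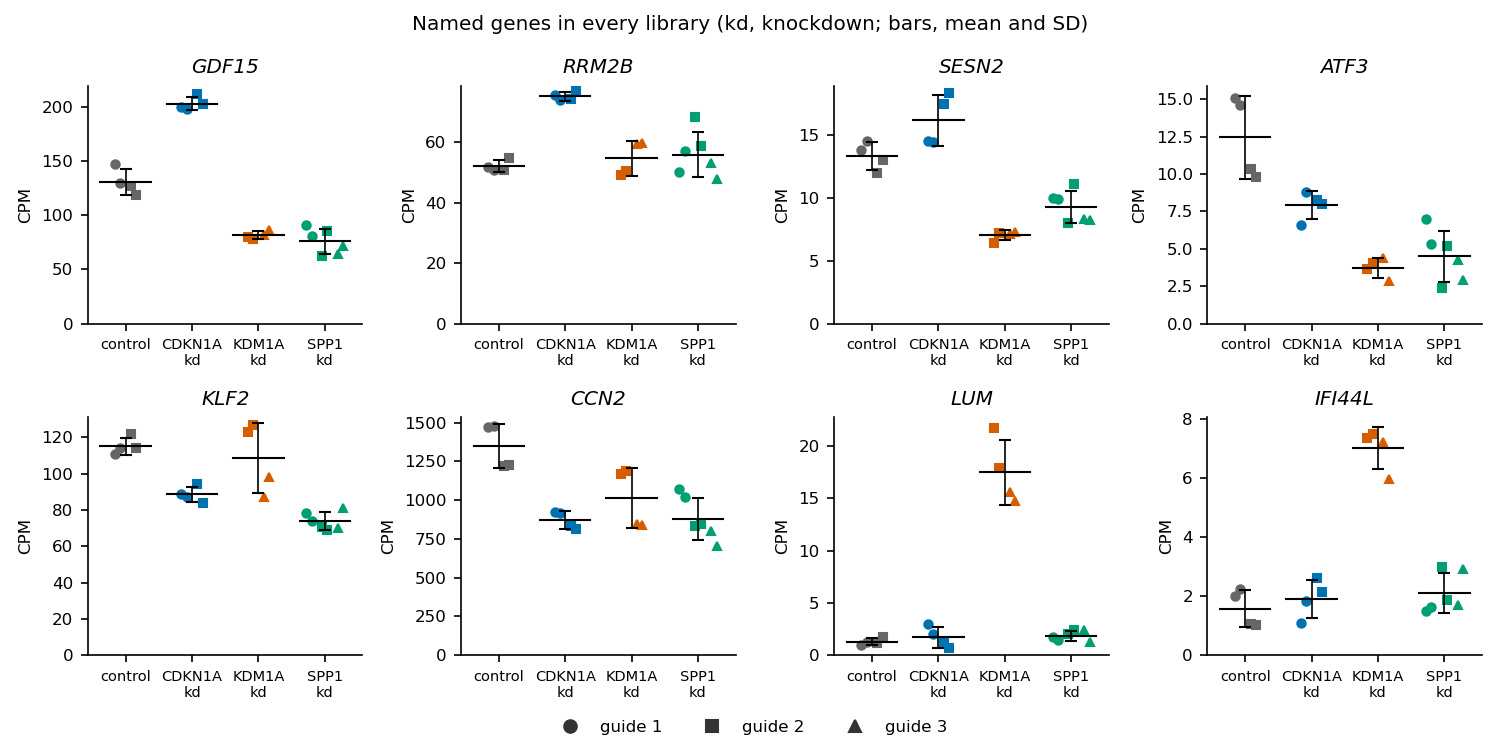
CPM of 8 named genes in every library, by group, with marker shape for the guide and bars for the mean and SD (n = 4, and 6 for SPP1 knockdown). GDF15 lies at 203 ± 6.24 CPM in the CDKN1A knockdown against 131 ± 11.4 in control, and KLF2 at 73.9 ± 4.9 CPM in the SPP1 knockdown against 115 ± 4.61 in control.

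Guides against the same gene were compared to see how far their effects matched. The KDM1A guides differed in contractile and matrix genes. ACTA2, smooth muscle actin, averaged 300 ± 10 CPM with guide 2 and 70.6 ± 2.91 CPM with guide 3 (SD, n = 2 each), against 88.7 ± 26.2 CPM in control (guide 3 minus guide 2, log2 -2.09 ± 0.17, adjusted p 4.23e-06). COL4A1 averaged 1560 and 614 CPM against 1230 in control (log2 -1.35 ± 0.05, adjusted p 1.96e-09), and elastin, ELN, 14.5 and 1.14 CPM against 2.21. Of 15 contractile genes 12 were lower with guide 3 (13 adjusted over the list alone; median -0.44, adjusted p 4.59e-15, or adjusted p 0.0579 with an estimated correlation). Of 26 matrix genes 17 were lower (2 higher and 19 lower adjusted over the list alone; median -0.41, adjusted p 9.01e-17, or adjusted p 0.0579 with an estimated correlation). TGF-beta and YAP targets were lower in 10 of 26 (12 adjusted over the list alone; adjusted p 4.87e-08, or adjusted p 0.0718 with an estimated correlation). The neurofilament NEFM was higher with guide 3, at 144 against 45.1 CPM. Against control, the contractile list passed upward without guide 3 and downward without guide 2 (adjusted p 6.09e-04 and 0.00128). Both are at the preset correlation only, and with all libraries the list had adjusted p 0.858, or adjusted p 0.938 with an estimated correlation.

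Among the CDKN1A guides, iron storage and NRF2 targets were higher with guide 2 in 5 of 11 (11 adjusted over the list alone; median 0.27, adjusted p 6.34e-16, and adjusted p 0.0102 with an estimated correlation). The integrated stress response was higher with guide 2 in 4 of 14 and lower in 0 (10 higher adjusted over the list alone). Its median was 0.31, with adjusted p 7.43e-11, or adjusted p 0.0857 with an estimated correlation. Between the SPP1 guides, cholesterol synthesis genes were higher with guide 3 than guide 1 in 8 of 21 (18 adjusted over the list alone; median 0.32, adjusted p 7.84e-12, and adjusted p 0.0403 with an estimated correlation). The control guides differed in p53 targets, 2 of 23 lower with guide 2 (1 higher and 8 lower adjusted over the list alone; median -0.18, adjusted p 8.38e-05, and adjusted p 0.0403 with an estimated correlation). In number, 834 genes differed between the KDM1A guides, 548 of them lower with guide 3, against 173 between the CDKN1A guides, 450 among the SPP1 guides and 183 between the control guides. Leaving out 1 of the 4 KDM1A libraries gave 279 to 325 for KDM1A. Which guides differed most depends on the setting, as the SPP1 guides gave 1609 without a filter and 2581 without SPP1 guide 3 replicate 1. The log2 fold changes of 2 guides of 1 target correlated across genes with r 0.41 for CDKN1A, 0.55 for KDM1A and 0.39 to 0.47 for SPP1. All guides were set against the same control libraries, which alone correlates fold changes, so this r does not by itself show a shared effect. Between knockdowns of different targets, over all their libraries and with the same controls, r was 0.32 to 0.46.

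**Figure D5:**
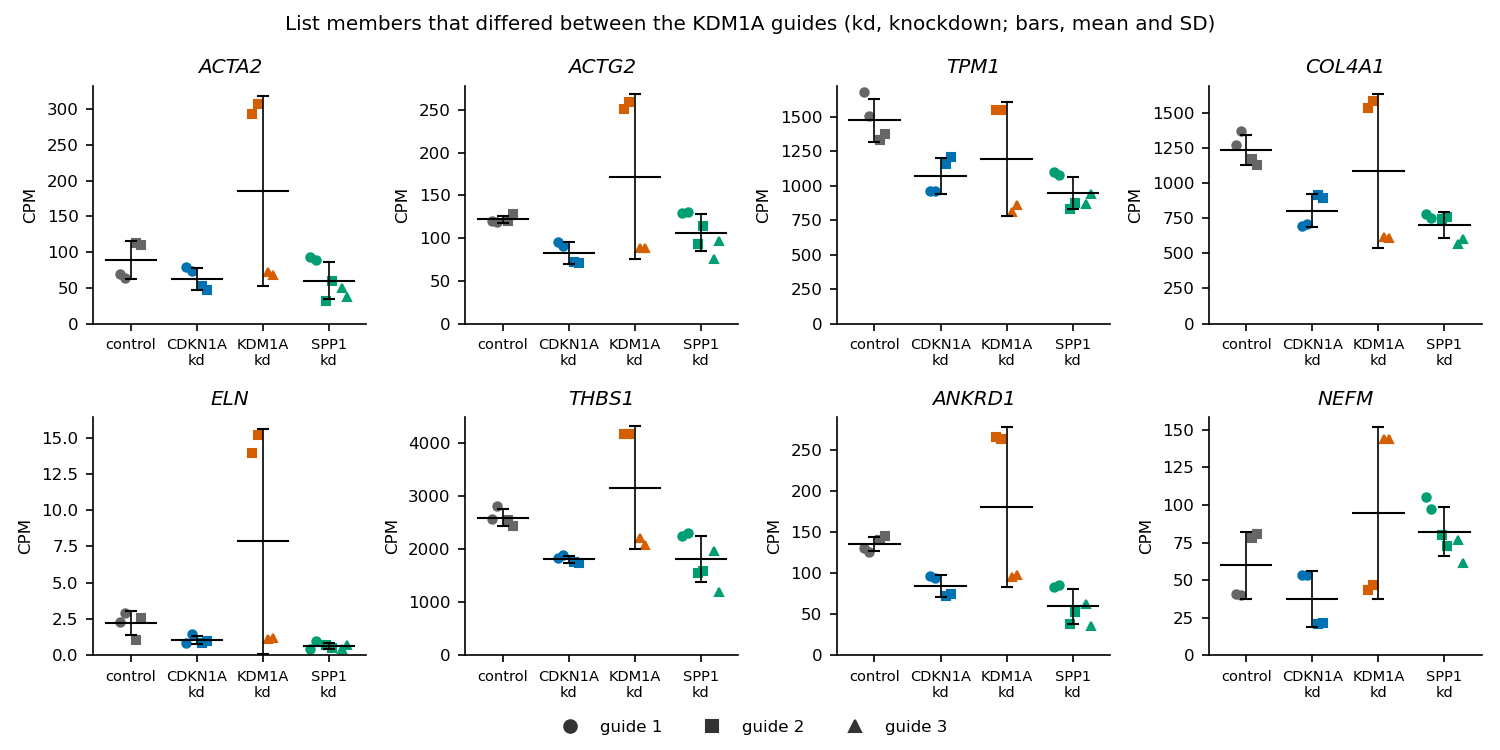
CPM of 8 list members that differed between the KDM1A guides, in every library, by group, with marker shape for the guide and bars for the mean and SD (n = 4, and 6 for SPP1 knockdown). ACTA2 lies at 300 CPM with KDM1A guide 2 and 70.6 CPM with guide 3, on both sides of the control mean of 88.7 CPM.

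Some genes moved in 1 direction in all 3 knockdowns. CCN2 averaged 1350 ± 146 CPM in control and 914 ± 145 CPM over the other libraries. EPGN went from 3.03 ± 1.36 to 9.22 ± 3.77 CPM, and the ETS factor ETV1 from 14.1 ± 1.57 to 23.7 ± 4.78 CPM. Higher in all 3 were 15 genes (0.188 expected if calls were independent), among them EPGN, TMCC3, GPAT3, ETV1, ANGPTL4, MOXD1, MAML3, PERP, CTPS2, APOBEC3C, NXPE3, PARP4, SLC20A1 and ASAH1. Lower in all 3 were 8 (0.142 expected), among them FOSB, FOS, SLFNL1, CCN2, WTIP, TRMT61A and FHL2. Of these 15 and 8 genes, 4 differed between the control guides, as did 1.35% of all genes. FOS and FOSB averaged 8.89 and 5.53 CPM in control guide 2, against 8.19 and 4.22 CPM over the knockdown libraries. The pairs shared 31 rises and 27 falls (CDKN1A and KDM1A; 7.84 and 4.62 expected), 23 and 21 (CDKN1A and SPP1; 3.52 and 3.8) and 126 and 112 (KDM1A and SPP1; 17.3 and 15.4). These expected counts leave out the shared controls. Simulated data that keep them had 0 genes called in both, or 2.7, 2.85 and 3.05 with guide effects, but hold no knockdown effects and so hardly any calls to share. With a control guide of its own for each knockdown, in the 2 ways of assigning them, shared rises were 13 and 2, 1 and 0, and 2 and 35 in this order, and shared falls 10 and 2, 1 and 1, and 4 and 24. Such fits made few calls in places, 289 or 51 for CDKN1A, 445 or 1333 for KDM1A and 18 or 774 for SPP1, which limits the overlap.

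The control libraries are common to these comparisons, and that alone correlates fold changes. Across genes r was 0.32 for CDKN1A and KDM1A, 0.43 for CDKN1A and SPP1 and 0.46 for KDM1A and SPP1, while simulated data without shared effects gave 0.5, 0.55 and 0.55, a value that real effects of each knockdown dilute. The covariance was 0.0383, 0.0387 and 0.0546 against a simulated 0.0326 in each pair, or 0.0477, 0.0464 and 0.0461 with guide effects. With a different control guide for each knockdown r was 0.04, 0.06 and 0.13. Control guide 2 lay nearer to the knockdowns than control guide 1 for 20 of the 23 genes that moved in all 3.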

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

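Tests chosen only after the result was seen are the length trend and the link to SPP1 mRNA in the libraries that stand apart, the expression level above which genes entered both, the test of the larger KDM1A loss, and the test of the shared control libraries.

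In 2 guides the replicates differed far more than sampling explains: SPP1 guide 3 (chi-square per degree of freedom 16.7) and control guide 1 (10.7), against 2.15 to 5.35 in the other 7 guides. Over the 9478 genes with a mean log2 CPM above 3, the replicate difference of SPP1 guide 3 correlated with log2 transcript length at r -0.52 and that of control guide 1 at 0.59, against at most 0.26 in size in the other guides. Over all tested genes these were -0.22, 0.23 and at most 0.09. GC content does not account for it (r 0.16 for SPP1 guide 3, against up to 0.44 in guides that do not stand apart). Control guide 1, whose SPP1 mRNA shows no such loss as in SPP1 guide 3 replicate 2, had the mirror pattern. The r between the 2 replicate differences was -0.53, against at most 0.21 in size for other pairs. Over all tested genes these were -0.12 and 0.11, which hardly differ in size. Low SPP1 mRNA would not give the part shared with control guide 1. An effect of it on the rest cannot be excluded, since both differences follow length, which alone can give a negative r. A length-dependent difference in RNA or library preparation is therefore a candidate explanation, and a difference in culture state was not tested.

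The guides of a target differed in 183 genes for control, 173 for CDKN1A, 834 for KDM1A and 450 for SPP1. For KDM1A, the stronger loss of KDM1A mRNA with guide 3, if the protein follows the mRNA, would push genes further in the direction of the knockdown, but only 41.6% of the 834 differences had that sign. A length trend is argued against, since 1216 genes differed with it removed. Effects of 1 guide outside KDM1A, and the state of the cells at collection, may each account for the difference, and neither was tested.

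Log2 fold changes correlated between the knockdowns (r 0.32, 0.43 and 0.46). The covariance lay above that simulated without shared effects (differences 0.00575, 0.00614 and 0.0219), but with guide effects in the simulation the difference was -0.00938 and -0.00772 for the CDKN1A pairs and 0.00851 for KDM1A and SPP1. With a different control guide for each knockdown at most 44.3% of the covariance remained, so the shared control libraries could account for most of it. A length trend does not, since at least 99.4% remained with the trend removed. A response common to the knockdowns stays open, most of all for KDM1A and SPP1.

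List medians moved apart between knockdowns by a test of the difference. For p53 targets this was log2 0.44 (CDKN1A minus KDM1A) and 0.41 (CDKN1A minus SPP1), with adjusted p 0.0193 with an estimated correlation in both. The others did not pass with an estimated correlation: the integrated stress response by 0.86 and 0.55 in the same order (adjusted p 0.217 and 0.195 with an estimated correlation), and for CDKN1A minus SPP1 G2/M by 0.21 (0.238) and iron storage and NRF2 targets by 0.29 (0.301). Against control the iron list had adjusted p 0.757 without CDKN1A guide 2.

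Single libraries stood away from the others of their group in 16 of 368 groups of values, where chance gives about 1 in 20. SPP1 guide 3 replicate 1 had 2.54% of counts without a gene (others 2.51 to 2.52), and KDM1A guide 3 replicate 2 had 1.96% in mitochondrial genes (others 2.32 to 2.36). In CPM, control guide 1 replicate 1 stood apart in MT-CO1 (5280; others 5970 to 6110) and PODXL (741; others 786 to 794), and control guide 1 replicate 2 in HIST2H2AA3 (0.418; others 0) and GDF5 (1.95; others 2.58 to 2.7). Control guide 2 replicate 1 did so in TAP2 (15.2; others 0.207 to 0.488), and control guide 2 replicate 2 in PERP (70.9; others 56.9 to 58.8), SNAI1 (5.44; others 4.29 to 4.36) and BAG6 (52; others 9.58 to 16.3). The CDKN1A libraries had KRT8 at 55.2 (guide 1 replicate 1; others 57.8 to 58.3), ITGA5 at 465 (guide 2 replicate 1; others 447 to 450) and CCNB2 at 61.5 (guide 2 replicate 2; others 66.4 to 67.1). HDAC1 was 119 in KDM1A guide 2 replicate 1 (others 113 to 114), TMEM132B 13.6 in SPP1 guide 3 replicate 1 (others 7.29 to 8.59) and LDHA 1730 in SPP1 guide 3 replicate 2 (others 1430 to 1510).

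Only 1 split of the libraries, the real one, gave as many called genes in each of the 6 comparisons, a share under 0.05. These splits count the libraries of a guide as separate samples, although 15 of 18 libraries lay closest to one of the same guide. Chance is therefore not excluded. The highest counts of the other splits were 7 against 271 for CDKN1A, 30 against 1225 for KDM1A and 57 against 2026 between these knockdowns, from 35 splits each. For the comparisons with SPP1, 100 of 210 possible splits were run. There the highest counts of the other splits were 14 against 738 for SPP1, 273 against 1634 between CDKN1A and SPP1, and 82 against 1606 between KDM1A and SPP1. Among the splits run, those that keep both libraries of a guide together number 2 to 8 per comparison, too few for a share under 0.05. The highest counts of 7, 30, 57 and 273 came from such splits. With guides summed CDKN1A and SPP1 kept 1 call each.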

How the results depend on the processing

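Leaving out the 2 libraries that stand apart was chosen after seeing the data; the other alternatives were chosen before the data were examined. The cause was not tested for any change below, except that leaving out or summing libraries leaves fewer samples, no filter tests more genes, and an estimated correlation widens the list test.

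Calls of the CDKN1A comparison (271) became 561 with DESeq2, 71 with a length offset, 172 with a replicate block, 587 with the 2 groups alone, 1 with guides summed, and 42, 127 and 44 without control guide 1, CDKN1A guide 1 and CDKN1A guide 2. Those of KDM1A (1225) became 570 with a length offset, 162 with guides summed, 417 without control guide 1 and 747 without KDM1A guide 2. Of these 65.4% and 82.1% were rises with the offset and summed, against 58.9%. Those of SPP1 (738) became 304 with a length offset, 390 with the 2 groups alone, 1 with guides summed, 293 without the 2 libraries, and 7, 276 and 432 without control guide 1, SPP1 guide 2 and SPP1 guide 3. CDKN1A against KDM1A (2026) gave 987 with a length offset, 436 summed, and 1349, 668 and 951 without CDKN1A guide 1, CDKN1A guide 2 and KDM1A guide 2. CDKN1A against SPP1 (1634) gave 765, 111 summed, and 912 and 299 without CDKN1A guides 1 and 2. KDM1A against SPP1 (1606) gave 762, 998 with the 2 groups alone, 245 summed and 260 without KDM1A guide 2.

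Leaving out 1 library gave 54 (without CDKN1A guide 2 replicate 2) to 446 (SPP1 guide 3 replicate 2) for CDKN1A, 774 (control guide 1 replicate 2) to 1449 (SPP1 guide 3 replicate 2) for KDM1A and 184 (control guide 1 replicate 2) to 753 (SPP1 guide 3 replicate 2) for SPP1. Between knockdowns it gave 1293 (CDKN1A guide 2 replicate 2) to 2375 (SPP1 guide 3 replicate 2), 863 (CDKN1A guide 2 replicate 2) to 1740 (SPP1 guide 2 replicate 1) and 775 (KDM1A guide 2 replicate 2) to 1595 (control guide 1 replicate 1). Differences between guides went from 26 (without control guide 2 replicate 2) to 464 for control, 48 (CDKN1A guide 1 replicate 1) to 338 for CDKN1A and 279 (KDM1A guide 2 replicate 2) to 1199 for KDM1A, each highest without SPP1 guide 3 replicate 2. For SPP1 they went from 83 (SPP1 guide 1 replicate 1) to 2581 (SPP1 guide 3 replicate 1). The lone library of a guide is there assumed to vary like the rest. Without a filter they were 590 for control, 507 for CDKN1A and 1609 for SPP1.

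CDKN1A mRNA lost its call with guides summed (log2 -0.78, adjusted p 0.32) and without control guide 1 (-0.66, 0.0834), the range over its alternatives being 7.09e-07 to 0.32; 1 library left out gave -0.88 to -0.67. KDM1A mRNA passed in all alternatives run (adjusted p up to 0.0145), with 1 library left out at -1.01 to -0.82. SPP1 mRNA passed with no filter (-0.7, 0.0322), without SPP1 guide 2 (-0.92, 0.0495) or 3 (-0.76, 0.039) and without SPP1 guide 3 replicate 1 (-0.89, 0.0248), in a range of 0.0248 to 0.313; 1 library left out gave -0.89 to -0.58 (SPP1 guide 3 replicate 2).

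Of 189 named values 163 were called; 108 were with a length offset, 26 summed, 105 without the 2 libraries, 52 without control guide 1, and 95 (without control guide 1 replicate 2) to 158 (SPP1 guide 3 replicate 2) with 1 library left out. None of the 161 called genes other than targets reversed in any alternative run, and 138 lost the call in at least 1. Reversed, none of them called, were TAP2 in CDKN1A knockdown against control (-3.54 without control guide 1 replicate 1 to 0.35 without control guide 2 replicate 1, and 0.41 without control guide 2) and MITF, with a length offset in CDKN1A (-0.46) and KDM1A (-0.21), and in SPP1 (-0.3 without control guide 2 replicate 1 to 0.1 without control guide 1 replicate 2, and 0.25 without control guide 1). Lists that reversed, with adjusted p, were iron storage and NRF2 targets in CDKN1A without CDKN1A guide 2 (0.757), and in KDM1A G1/S without KDM1A guide 3 (0.0242) and contractile and matrix genes without KDM1A guide 2 (0.00128 and 0.0221). List tests went from 24 to 0 with an estimated correlation. The r between knockdowns became 0.04, 0.06 and 0.13 with controls split and 0.45, 0.55 and 0.56 without the 2 libraries. Small changes are missed: on simulated data 32 to 46% of the smallest were recovered.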

Other observations

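Markers of other skin cells moved only as single genes. PERP was higher in all 3 knockdowns (log2 0.27, 0.8 and 0.27 for CDKN1A, KDM1A and SPP1), but it was the only called one of the 4 measured keratinocyte markers. Of 4 measured endothelial and leukocyte markers TEK alone was called, lower in the SPP1 knockdown (log2 -0.39 ± 0.09), and neither of the melanocyte markers measured was called. The 13 mitochondrial mRNAs had 0 calls in each knockdown.

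Single genes of several lists also differed between the KDM1A guides and were picked after seeing the data. The protease list itself did not pass, with 2 of 13 higher and 2 lower in guide 3 (3 and 3 adjusted over the list alone; adjusted p 0.73, or adjusted p 0.828 with an estimated correlation). MMP1 averaged 6010 CPM with guide 2 and 11700 CPM with guide 3 against 6310 CPM in control, and THBS1, thrombospondin 1, 4160 and 2150 CPM against 2590 CPM. HMOX1 averaged 41.2 and 23.7 CPM, and ANKRD1, a YAP target, 265 and 96.2 CPM against 136 CPM in control.

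The difference between transcript length and effective length follows the fragment lengths. Its median over the longer transcripts was 223.3 and 209.6 bases in the SPP1 guide 2 libraries and 204.7 in SPP1 guide 3 replicate 2, against 185.7 to 197.1 in the others.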
